A study of Mus musculus with 8 samples.

How the data were processed

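Ribosome-associated RNA was measured in 8 libraries from mouse skin. The mice carried AdipoqCreER, a tamoxifen-inducible recombinase driven from the adiponectin gene, and NuTRAP, a reporter that tags ribosomes with GFP in cells where the recombinase has acted. Per the labels' protocols, mice 7 to 9 weeks old received 4 full-thickness wounds with a 5 mm punch, RNA was recovered from GFP-tagged polysomes with an antibody against GFP, and libraries were made from 20 ng of RNA. Groups were read from the sample titles: uninjured skin (n = 3), and skin titled as 3 days (n = 2) and 7 days (n = 3) post wounding, where the abbreviation in the titles was read as days after wounding. Libraries of input or unbound RNA were not used here.

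The values analysed were raw read counts per gene as deposited by the authors, with replicates in separate columns and no normalization. Counting was done with featureCounts 2.0.8, per the file headers. STAR 2.7.10b, featureCounts, DESeq2 and the build mm10 are named, per the submitters' processing notes. The strand setting and the treatment of reads matching several genes are not given in the sources used here, so counts of overlapping, antisense and near-identical genes (such as Hbb-bs and Hbb-bt, or Hspa1a and Hspa1b) are uncertain. Of 53700 gene identifiers, 52093 were matched to symbols through the GRCm38 annotation (GENCODE M21) and 1607 were not, and the unmatched ones held 0.053% to 0.493% of a library's counts. Only 1543 of the 52147 identifiers found in that annotation had the same start coordinate there. Coordinates below are therefore those of the deposited table, and their build is not settled by the sources used here.

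Counts were normalised by the trimmed mean of M values (TMM) and tested with edgeR 4.0.16 in R 4.3.3. Genes passing edgeR's expression filter at a minimum count of 10 were kept, which left 18656. A model with 1 mean per group was fitted over all 8 libraries (5 residual degrees of freedom), and the 3 contrasts were tested, two-sided, with the quasi-likelihood F test and Benjamini-Hochberg adjustment at 0.05. Standard errors of log2 fold changes were taken from the fold change and its F statistic. CPM values are TMM-normalised counts scaled to a common library total, given as mean ± SD. For a gene without a count in a whole group, the fold was bounded with 3 counts per library, which is 0.169 to 0.5651 CPM before normalization. This bound covers counting error only. The libraries held 5308959 to 17751689 counts, so the shallowest had the least precision for low genes.

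The tests, the alternatives, 31 gene lists and the rule for naming genes were set before the data were examined. Per contrast, genes were named (a) when they were among the 8 with the largest rise or the 8 with the largest fall that passed the test, reached a mean of 20 CPM in the higher group, had no overlap between libraries of both groups and bore an established gene symbol; (b) when they belonged to a fixed set of adipocyte, PDGF, matrix and fibroblast genes; or (c) as up to 4 members with the smallest adjusted p of each list described, or any member of a list in which at most 5 passed. Other genes are named as chosen later. Lists were tested with camera (limma 3.58.1), which sets a list against all other genes, at a preset correlation of 0.01, adjusted over the lists of a contrast. The tests were repeated with an estimated correlation and with fry, which tests whether the members of a list move on balance one way. Further lists of luminal epithelial, nuclear and imprinted genes were drawn up once levels of some of their genes were known and are used only in the closing part. Member counts are given adjusted over all genes and adjusted over the list alone.

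The procedure was tested on simulated data in 3 runs per contrast. They were made from the real dispersions and library sizes and, for all groups, the means of the uninjured libraries. Genes to be changed were drawn only from those above a minimum level in uninjured libraries. The shares recovered therefore apply to such genes, and recovery of genes with lower levels, which include some named below, was not tested. At day 7 against uninjured, 12.7% of genes changed 2-fold (38 of 300) and 85.3% of genes changed 4-fold (256 of 300) were recovered, with 23 false calls. At day 3 against uninjured the shares were 6.0% and 75.3% (18 and 226 genes), with 15 false calls. At day 7 against day 3 they were 8.33% and 76.7% (25 and 230 genes), with 24 false calls. Recovered genes and false calls are totals over the 3 runs, so false calls are to be set against the recovered genes. Means of 16759, 16785 and 16729 genes were tested per run. In the same simulation at day 7, camera found a list raised 2-fold in 3 of 3 runs and called 1 of 87 unchanged lists. Genes were simulated independently, so false calls among lists of correlated genes were not tested.

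Alternatives were DESeq2 size factors and upper-quartile scaling in edgeR, no filter, a filter of 5 CPM in 2 libraries, the DESeq2 1.42.0 Wald test, limma-voom, fits on only the 2 groups compared, the replicate number as a block, a fold threshold of 1.5, removal of abundant background genes and leaving out each library. A covariate for luminal epithelial RNA and a simulation of an unchanged day 3 beside the measured day 7 were added after seeing the data. The columns of the table carry 3 prefixes, 1 for each group, so a batch marked by the prefix and the group cannot be told apart. The labels do not say whether libraries of a group came from separate animals or pools, so p-values measure only the spread between these samples, which may be technical. Pairs of libraries within a group differed by a chi-square of 24.0 to 65.2 per gene, and each library was counted as 1 sample.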

Results

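RNA pulled down with GFP-tagged ribosomes, a tag placed in cells marked by AdipoqCreER, was profiled in uninjured mouse skin (n = 3) and in skin 3 days (n = 2) and 7 days (n = 3) after excisional wounding. The pull-down also held RNA of genes of other cell types. In uninjured libraries the muscle gene Tnnt3 was at 1102 to 2410 CPM and the adipocyte gene Plin1 at 849 to 876 CPM. Values below are therefore of the recovered RNA and not of adipocytes alone. The series title places the question in the passage of adipocytes to a fibroblast state during repair and in the part that PDGF signalling has in it. Uninjured libraries held 8653671, 17751689 and 7883909 counts, day 3 libraries 5308959 and 9585689, and day 7 libraries 6763290, 9292594 and 8832209. Between 24301 and 29823 genes had at least 1 count. The common biological coefficient of variation was 31.5% within uninjured, 38.8% within day 3 and 38.5% within day 7 libraries.

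The first principal component held 47.7% of the variance and separated uninjured libraries (-92.91 to -41.02) from day 7 replicates 1 and 2 (113.57 and 82.46). Day 7 replicate 3 lay at 8.43 on that component, beside the day 3 libraries at 1.90 and 4.96. Day 3 replicate 1 stood apart on the second component (15.9% of the variance) at -97.72, where the other libraries lay between -11.32 and 30.33.

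**Figure D1:**
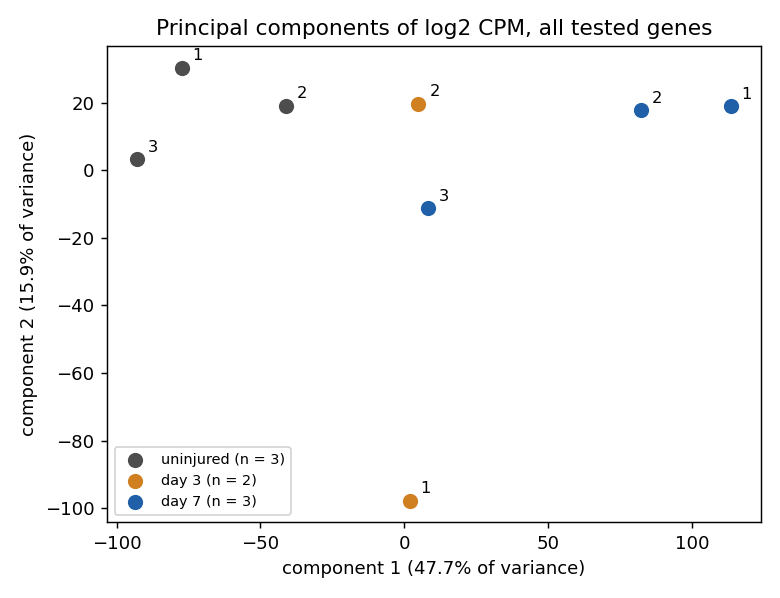
Principal components of log2 CPM over the 18656 tested genes, with component 1 on the horizontal and component 2 on the vertical axis; each point is 1 library, numbered by replicate and coloured by group. Uninjured libraries lie between -92.91 and -41.02 on component 1, day 7 replicate 3 lies at 8.43, and day 3 replicate 1 lies at -97.72 on component 2.

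At day 7 against uninjured skin, most measured genes of the fibrillar matrix rose. Postn, a matricellular protein of healing tissue, rose 42.4-fold, from 13.3 ± 4.95 CPM (SD, n = 3) to 570.5 ± 155 CPM (n = 3), a log2 fold change of 5.41 ± 0.37 (SE) with an edgeR adjusted p of 7.99e-05. The chains of type I collagen, Col1a1 and Col1a2, rose 16.9-fold (129.7 ± 22.3 to 2197 ± 786 CPM, adjusted p = 0.000944) and 13.5-fold (188.6 ± 47.5 to 2555 ± 798 CPM, adjusted p = 0.00182). Col3a1 rose 3.94-fold from a higher uninjured level of 794 ± 66.6 CPM, and Fn1, which encodes fibronectin, rose 8.07-fold. Of 29 tested matrix and matrix assembly genes, 20 rose, 0 fell and 9 did not pass (25 rose and 1 fell adjusted over the list alone). Their median log2 fold change was 2.10 (camera adjusted p = 3.50e-26, adjusted p = 0.347 with an estimated correlation). Bgn, the proteoglycan biglycan, rose 10.5-fold. Col3a1 lost its call in every fit without 1 uninjured or day 7 library except that without day 7 replicate 3 (highest adjusted p = 0.130). In the same contrast, endothelial and macrophage markers had medians of 2.28 and 1.78 and skeletal muscle markers of -2.35. In the table, Postn (ENSMUSG00000027750.17) spans chromosome 3 from 54268530 to 54298458 and Col1a1 (ENSMUSG00000001506.11) chromosome 11 from 94827050 to 94843868.

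Some genes of matrix turnover and of contractile cells rose too. Among 20 proteases and inhibitors, 10 rose and 0 fell (15 and 0 adjusted over the list alone), with a median log2 fold change of 2.17 (camera adjusted p = 3.95e-12, adjusted p = 0.358 with an estimated correlation). The stromelysin Mmp3 rose 14.0-fold, the gelatinase Mmp2 7.05-fold and the membrane-bound Mmp14 8.57-fold. The collagenase Mmp13 had no count in the uninjured libraries and 7.60 ± 2.75 CPM at day 7, at least 23.2-fold higher. Of 17 contractile and myofibroblast genes, 10 rose and 2 fell (11 and 3 adjusted over the list alone, camera adjusted p = 5.40e-05, adjusted p = 0.439 with an estimated correlation). Acta2, smooth muscle actin, rose 10.4-fold (14.2 ± 5.47 to 149.8 ± 102 CPM), Tagln rose 13.6-fold, Cdh11 6.27-fold and Lrrc15, a surface protein of activated fibroblasts, 47.9-fold. Acta2, Tagln and the vascular mural gene Myh11 (5.11-fold at day 7) were higher in day 3 replicate 1 (116.8, 9.25 and 20.56 CPM) than in replicate 2 (36.56, 3.31 and 8.02 CPM), whereas Col1a1, Col3a1 and Fn1 were lower in it. Tpm1 and Tpm2, tropomyosins that skeletal muscle also makes, fell by 1.47 and 1.78 on the log2 scale.

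Fibroblast and progenitor markers rose in part. Of 19 tested, 6 rose and 0 fell (8 and 1 adjusted over the list alone), with a median log2 fold change of 0.88 (camera adjusted p = 0.00496, adjusted p = 0.439 with an estimated correlation). Cd9 rose 6.53-fold and Clec3b 6.58-fold. In day 3 replicates 1 and 2, Cd9 was at 123.38 and 54.95 CPM, against at most 33.42 CPM in uninjured libraries. This split has the direction of that of the epithelial keratin Krt8 (329 and 0.64 CPM), whereas Clec3b was at 11.93 and 11.12 CPM. Dlk1, a surface protein that restrains adipocyte differentiation, rose 28.3-fold from 0.122 ± 0.123 CPM. Cd34, a progenitor surface marker also carried by endothelium, rose 3.21-fold (adjusted p = 0.0479), a call lost without uninjured replicate 1 or 3 or day 7 replicate 1 or 2 (highest adjusted p = 0.184). Ly6a was at 206 ± 37.0 CPM against 176 ± 76.9 CPM and did not pass (adjusted p = 0.685).

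Among 21 genes of PDGF signalling, 3 rose and 0 fell, over all genes and also adjusted over the list alone. The receptor Pdgfrb rose 4.62-fold, from 6.16 ± 2.74 to 28.7 ± 15.1 CPM (log2 2.21 ± 0.50, adjusted p = 0.0260). The ligand Pdgfb rose 5.64-fold (2.06 ± 1.03 to 11.7 ± 5.55 CPM, adjusted p = 0.0192). Pdgfrl, a receptor-like gene, rose 21.5-fold. Pdgfra was at 7.55 ± 3.33 CPM in uninjured and 18.4 ± 8.80 CPM in day 7 libraries (adjusted p = 0.119), and the ligand Pdgfa at 23.4 ± 5.03 and 34.9 ± 8.54 CPM (adjusted p = 0.235), and neither passed. The list as a whole had a median log2 fold change of 0.02 and was not called (camera adjusted p = 0.151). Pdgfrb lost its call without any 1 of the uninjured libraries or day 7 replicate 1 or 2 (highest adjusted p = 0.103), and Pdgfb without uninjured replicate 2 or 3 or day 7 replicate 1 or 2 (highest adjusted p = 0.0767). In day 7 replicates 1, 2 and 3, Pdgfrb was at 41.55, 32.57 and 12.10 CPM and Pdgfb at 15.40, 14.28 and 5.27 CPM. The endothelial gene Egfl7 was likewise lowest in replicate 3 (108.79, 97.88 and 23.60 CPM), whereas Pdgfrl was highest there (12.79, 20.62 and 22.52 CPM). The vascular mural cell genes Myh11 and Notch3, of cells that also carry Pdgfrb, rose 5.11-fold and 5.16-fold, in a list of 11 that was not called (camera adjusted p = 0.119). Both were lowest in day 7 replicate 3, as Pdgfrb was (6.95 CPM for Myh11 and 3.35 CPM for Notch3). In day 3 replicates 1 and 2, Myh11 was at 20.56 and 8.02 CPM and Notch3 at 17.68 and 9.52 CPM. Pdgfrb split the other way there, at 10.69 and 21.81 CPM. Pdgfrb (ENSMUSG00000024620.12) spans chromosome 18 from 61178222 to 61218133.

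Genes of adipocyte identity lay lower on average and none passed singly. Of 20 tested, 0 rose and 0 fell in edgeR or adjusted over the list alone, 3 had a positive fold change, and their median log2 fold change was -0.56 (camera adjusted p = 0.000477, adjusted p = 0.451 with an estimated correlation). Adipoq, the hormone adiponectin, was at 5238 ± 285 CPM in uninjured and 3256 ± 1735 CPM in day 7 libraries (log2 -0.69 ± 0.39, adjusted p = 0.277). The lipid droplet protein Plin1 was at 865 ± 14.4 and 548 ± 215 CPM (adjusted p = 0.181), and Pparg, the regulator of adipocyte differentiation, at 245 ± 40.6 and 141 ± 55.1 CPM (adjusted p = 0.105). Fasn, the fatty acid synthase, was at 3885 ± 1823 and 1455 ± 569 CPM (adjusted p = 0.0731). Fabp4 had a log2 fold change of 0.34 ± 0.43 and Lep of -0.06 ± 0.38. Within lipolysis (12 genes, 1 rose and 1 fell), Pnpla2, the first lipase of triglyceride breakdown, fell by 1.56 on the log2 scale (2353 ± 303 to 799 ± 449 CPM, adjusted p = 0.0397), and the receptor Adrb1 rose 5.80-fold. Pnpla2 lost its call without any 1 of the uninjured libraries or day 7 replicate 1 or 2 (highest adjusted p = 0.148).

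Day 7 replicate 3 differed from the others in these groups. Relative to the uninjured mean, its adipocyte identity score was 0.10 on the log2 scale, against -0.97 and -0.60 in replicates 1 and 2. Its endothelial score was 0.09 against 2.33 and 2.36, whereas its fibrillar matrix score was 1.89 against 2.24 and 2.71.

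**Figure D2:**
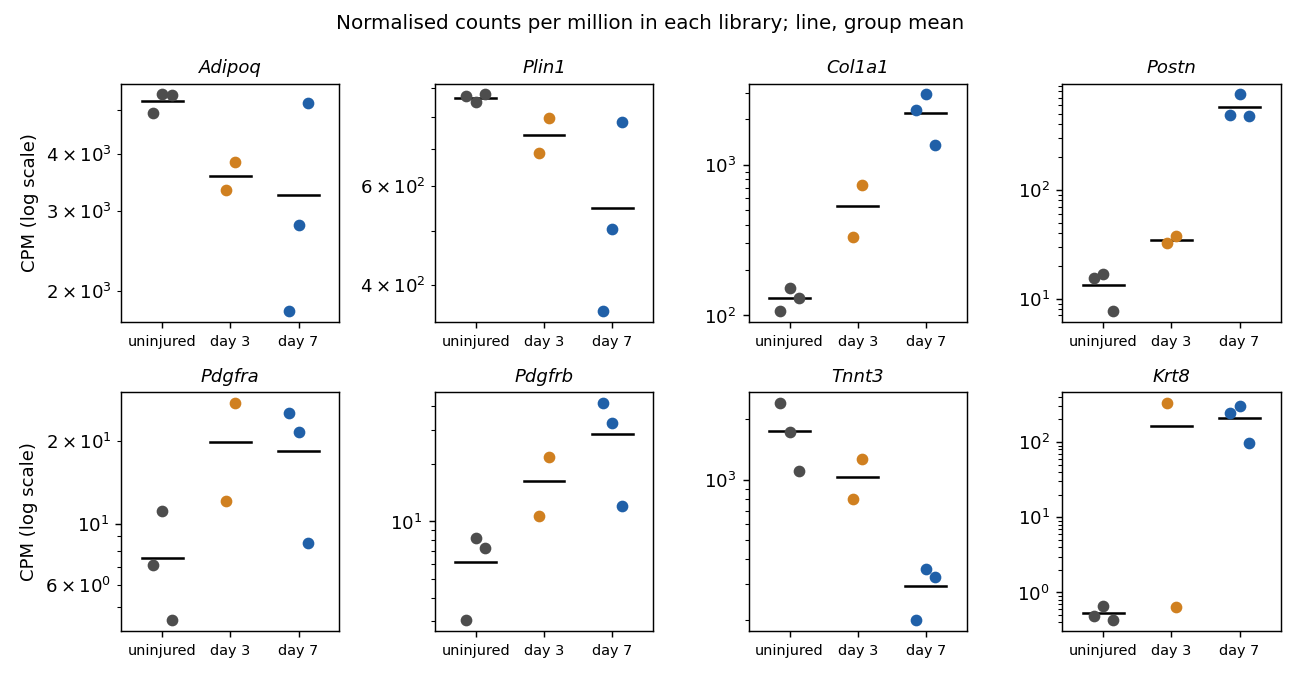
TMM-normalised CPM of 8 genes on log axes; each point is 1 library, each line a group mean, with uninjured (n = 3), day 3 (n = 2) and day 7 (n = 3) libraries from left to right. Postn rises from a mean of 13.3 to 570.5 CPM at day 7, day 7 replicate 3 has Adipoq at 5177 CPM, and Krt8 is at 329 CPM in day 3 replicate 1 and 0.64 CPM in replicate 2.

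Metabolic lists were called lower at the preset correlation with few single genes behind them. Fatty acid and triglyceride synthesis (20 genes, 0 passed, median -0.50, camera adjusted p = 0.00148) and fatty acid oxidation (19 genes, 0 passed, median -0.32, camera adjusted p = 0.00648) had an adjusted p = 0.465 with an estimated correlation. The nuclear genes of the respiratory chain had a median of -0.48 over 23 genes, of which Cox7a1, a subunit isoform abundant in muscle, fell by 2.10 on the log2 scale (list adjusted p = 0.000344, adjusted p = 0.465 with an estimated correlation). The unfolded protein response list had a median of -0.45 over 20 genes with 0 passing (camera adjusted p = 0.00234, adjusted p = 0.439 with an estimated correlation). Relative to the uninjured mean, scores in day 7 replicates 1, 2 and 3 were -0.83, -0.86 and 0.08 for synthesis and -0.77, -0.44 and 0.09 for oxidation. They were -0.84, -0.60 and -0.05 for the respiratory chain and -0.74, -0.35 and -0.18 for the unfolded protein response. Replicate 3 thus hardly shared the fall of the first 3 of these lists. Neither lipolysis (median -0.39, camera adjusted p = 0.103) nor glycolysis and hypoxia response (20 genes, 0 passed, median -0.27, camera adjusted p = 0.192) was called. In the latter, 4 genes rose and 3 fell adjusted over the list alone.

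Some inflammatory and interferon genes rose. Of 18 cytokine and chemokine genes, 8 rose and 0 fell (13 and 0 adjusted over the list alone), with a median log2 fold change of 2.31 (camera adjusted p = 1.50e-07, adjusted p = 0.358 with an estimated correlation). The monocyte attractant Ccl2 rose 7.89-fold to 8.51 ± 2.38 CPM, the eosinophil attractant Ccl11 3.80-fold to 17.1 ± 3.93 CPM and Tnf 14.9-fold to 2.35 ± 1.41 CPM. The neutrophil attractant Cxcl5 rose to a mean of 2.52 CPM from 3 counts over the uninjured libraries. Of 20 interferon response genes, 7 rose and 0 fell (9 and 0 adjusted over the list alone, median 1.43, camera adjusted p = 5.17e-06, adjusted p = 0.266 with an estimated correlation), among them Ifit1 (5.77-fold), Isg15 (3.38-fold), Oasl2 (4.53-fold) and Usp18 (4.02-fold). Of 22 cell cycle genes, 6 rose and 0 fell (16 and 0 adjusted over the list alone), including the survivin gene Birc5 (9.35-fold), the kinase Cdk1 (6.75-fold), Rrm2 (6.62-fold) and Mcm6 (3.01-fold), with a camera adjusted p = 2.50e-07 (adjusted p = 0.439 with an estimated correlation). Their score was 2.75 and 1.88 in day 7 replicates 1 and 2 and 0.54 in replicate 3.

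Of 18 Wnt ligands and targets, 3 rose and 0 fell (7 and 0 adjusted over the list alone, camera adjusted p = 0.000248, adjusted p = 0.358 with an estimated correlation). They were Sfrp2, a secreted Wnt modulator (0.382 ± 0.436 to 44.9 ± 23.0 CPM, 94.1-fold), Ccn4 (13.0-fold) and Dkk3 (7.31-fold). In the TGF-beta list, Ccn2, a matricellular target, rose 6.85-fold, the other 18 genes did not pass, and 7 rose adjusted over the list alone (camera adjusted p = 0.00448, adjusted p = 0.439 with an estimated correlation). Ccn2 was at 32.08 and 9.19 CPM in day 3 replicates 1 and 2, a split in the direction of that of Krt8. Of 13 basement membrane genes, Sparcl1 (5.35-fold) and Hspg2, the heparan sulfate proteoglycan perlecan (log2 1.44 ± 0.34), rose, with 6 rising adjusted over the list alone (camera adjusted p = 0.0768).

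Some markers of other cell types rose as well. Of 18 macrophage and monocyte genes, 7 rose and 0 fell (13 and 0 adjusted over the list alone, camera adjusted p = 3.84e-08, adjusted p = 0.439 with an estimated correlation), with Lyz2 at 391 ± 171 CPM (5.55-fold), Arg1 26.2-fold, Tyrobp 5.90-fold and Cd14 2.72-fold higher. The pan-leukocyte gene Ptprc was at 4.37 ± 1.18 and 11.5 ± 5.79 CPM and did not pass (adjusted p = 0.149). Of 14 endothelial genes, 8 rose and 0 fell (11 and 1 adjusted over the list alone, camera adjusted p = 1.37e-05, adjusted p = 0.439 with an estimated correlation), among them Egfl7 (6.56-fold), Cldn5 (7.38-fold), Flt1 (6.03-fold) and Eng (5.55-fold). Neutrophil genes S100a9 (13.0-fold), Clec4d (41.7-fold) and Ltf rose among 10 tested, and the mast cell genes Kit (16.7-fold) and Hdc (8.70-fold) among 7 (camera adjusted p = 0.00148 and 0.00139, each list with an adjusted p = 0.439 with an estimated correlation). Adjusted over the list alone, 4 neutrophil and 4 mast cell genes rose. In day 3 replicates 1 and 2, Ltf was at 121.74 and 0.64 CPM and Kit at 29.0 and 3.96 CPM, a split in the direction of that of the epithelial keratin Krt8 (329 and 0.64 CPM), whereas S100a9 was at 9.05 and 22.45 CPM.

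Smaller marker lists gave mixed results. Haemoglobin genes Hbb-bs (5.64-fold) and Hbb-bt (4.94-fold) rose among 5 erythroid genes (4 adjusted over the list alone, camera adjusted p = 0.00688, adjusted p = 0.439 with an estimated correlation). Of 11 pericyte and vascular smooth muscle genes, Myh11 (5.11-fold), Notch3 (5.16-fold) and Lmod1 (8.03-fold) rose and Des, the intermediate filament desmin, fell by 1.83 on the log2 scale (4 and 2 adjusted over the list alone, camera adjusted p = 0.119). Among 10 Schwann cell and melanocyte genes, Sox10 rose 20.1-fold (at 11.93 and 0.53 CPM in day 3 replicates 1 and 2, a split like that of Krt8) and Mbp fell by 1.11 on the log2 scale (2 and 1 adjusted over the list alone, camera adjusted p = 0.285). No gene passed among 8 of T, B and NK cells (median 1.08, camera adjusted p = 0.0843) or among 17 of keratinocytes and hair follicles (median 0.65, camera adjusted p = 0.167), over all genes or adjusted over the list alone.

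Most skeletal muscle genes fell at day 7. Of 16 tested, 0 rose and 12 fell (13 adjusted over the list alone), with a median log2 fold change of -2.35 (camera adjusted p = 4.47e-21, adjusted p = 0.266 with an estimated correlation). The fast troponins Tnnt3 (1745 ± 654 to 293 ± 83.3 CPM), Tnni2 (961 ± 405 to 128 ± 34.9 CPM) and Tnnc2 fell by 2.57, 2.91 and 2.56 on the log2 scale, and parvalbumin, Pvalb, by 2.40. The genes with the largest falls by the naming rule were mostly of muscle too. Apobec2, Myot, Hspb7, Trim63, Dusp13 and Hspb6, expressed in striated or other muscle, fell by 3.97, 3.77, 3.57, 3.52, 3.35 and 3.53 on the log2 scale, and the sialidase Neu2 by 3.34. The largest fall was of Pon1, a lipoprotein-associated esterase, by 4.29 (491 ± 218 to 25.1 ± 16.4 CPM, adjusted p = 0.00728).

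The largest rises by the naming rule were mainly of genes of luminal, that is glandular, epithelium. Krt8 and Krt19, keratins of simple epithelia, went from 0.532 ± 0.126 and 0.954 ± 0.295 CPM to 212 ± 104 and 304 ± 119 CPM (adjusted p = 0.0137 and 0.00745). The milk protein gene Csn3 had no count in the uninjured libraries and 23.1 ± 9.15 CPM at day 7, at least 70.6-fold higher (adjusted p = 0.0142). Tmprss2, the iodide transporter Slc5a5, the transcription factor Foxa1 and the tight junction gene Cldn3, with at most 3 counts in any uninjured library, rose to 50.3 ± 17.9, 45.5 ± 17.6, 31.1 ± 5.72 and 23.2 ± 4.66 CPM. Krt71, a keratin of the hair follicle sheath, was at 410 CPM in day 7 replicate 1, 13.0 and 4.19 CPM in the other day 7 libraries, and at most 0.55 CPM in uninjured ones. Krt8 was also at 329 CPM in day 3 replicate 1, against 0.64 CPM in day 3 replicate 2. Of the day 3 libraries, replicate 1 had the lower fibrillar matrix score (0.17 against 1.34). Krt8 lost its call without any 1 of the uninjured libraries (highest adjusted p = 0.0655).

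Lists of RNA quality moved as follows. Of 14 mitochondrially encoded genes, 4 rose (mt-Co1, mt-Co2, mt-Rnr1 and mt-Rnr2, 2.03-fold to 4.51-fold) and 0 fell, or 7 and 0 adjusted over the list alone (camera adjusted p = 0.000344, adjusted p = 0.439 with an estimated correlation), and they held 0.072% to 0.188% of counts at day 7 against 0.045% to 0.069% in uninjured libraries. Of 17 immediate early and stress genes, Fos (5.25-fold) and Hspa1b (5.79-fold) rose (4 adjusted over the list alone, camera adjusted p = 0.0124, adjusted p = 0.439 with an estimated correlation). Among 24 ribosomal protein genes, Rps12 rose 2.16-fold and Rpl10a, the gene whose GFP-tagged form marks ribosomes in NuTRAP, fell by 1.02 on the log2 scale (2 and 1 adjusted over the list alone, camera adjusted p = 0.118).

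Over all 18656 genes, 1101 were higher and 330 lower at day 7 than in uninjured skin (4987 at an unadjusted p under 0.05, against 933 by chance). The groups did not overlap for 30.2% of genes, where chance gives 10%. Camera called 16 lists higher and 6 lower at the preset correlation and 0 with an estimated correlation, and fry called 6. Those of fry were fibrillar matrix, matrix proteases, Wnt, cytokines and interferon response, all higher, and skeletal muscle, lower (fry adjusted p of 0.00904 to 0.0363). Among lists that fry did not call were adipocyte identity (fry adjusted p = 0.161), fibroblast markers (0.118), endothelial (0.114), cell cycle (0.102) and macrophage genes (0.0786). Of the 93 named genes that passed, 40 did so in each fit without 1 library, among them Postn, Col1a1, Fn1, Acta2, Mmp3, Pdgfrl and Tnnt3. The number of genes was 314, 809 and 468 without uninjured replicates 1, 2 and 3, and 393, 386 and 4055 without day 7 replicates 1, 2 and 3. It was 2501 with the DESeq2 Wald test, 794 with limma-voom, and 7 with a covariate for luminal epithelial RNA that was chosen after seeing the data.

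**Figure D3:**
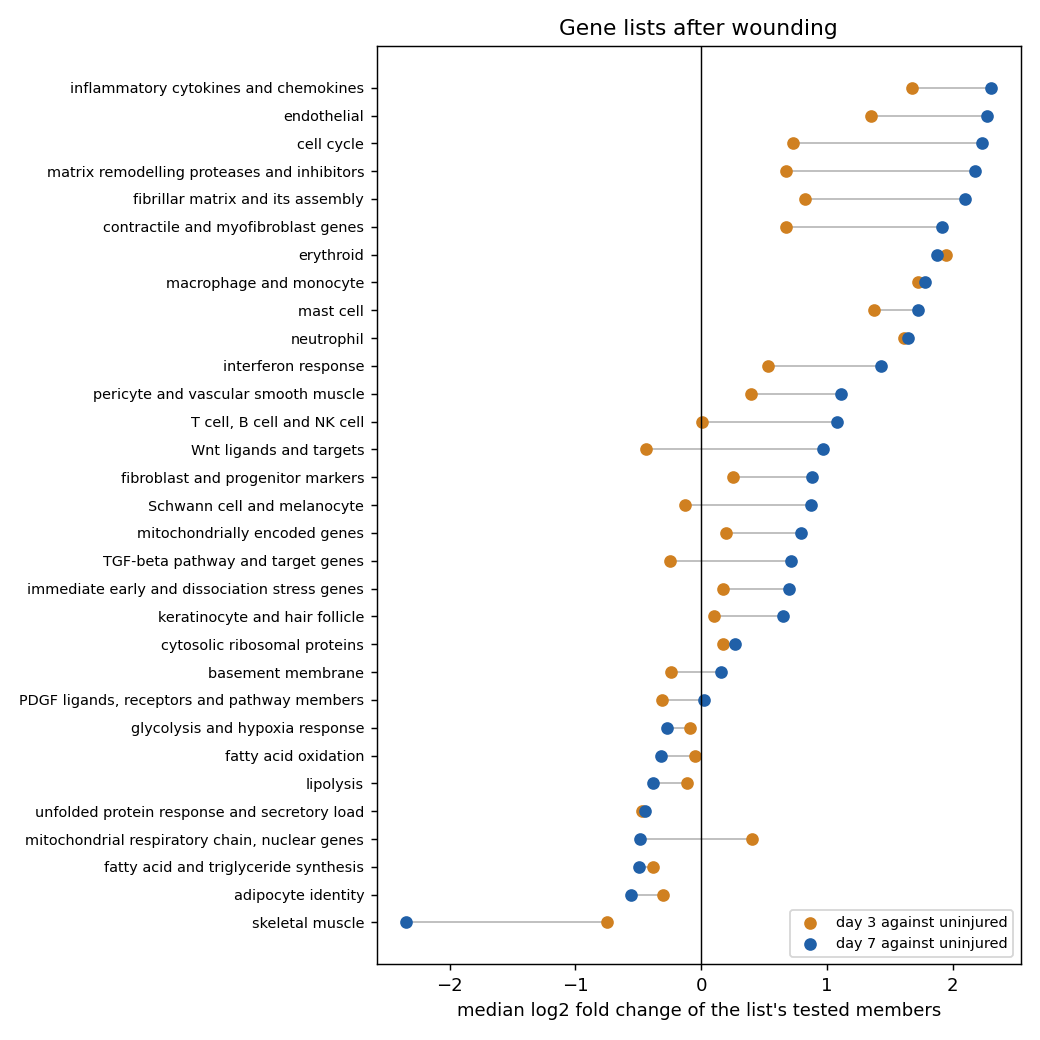
Median log2 fold change of the tested members of each of the 31 gene lists, on the horizontal axis, at day 3 (orange) and day 7 (blue) against uninjured libraries, with lists ordered by the day 7 value; a grey line joins the values of 1 list. The fibrillar matrix list lies at 0.83 and 2.10 and the skeletal muscle list at -0.75 and -2.35.

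At day 3 against uninjured skin, 2 genes passed, and both were higher. Slc5a5, the iodide transporter (ENSMUSG00000000792.3, chromosome 8 from 71335533 to 71345401), was at 49.4 and 7.59 CPM in the day 3 libraries and at most 0.14 CPM in uninjured ones (adjusted p = 0.0436). Gpihbp1, which carries lipoprotein lipase across capillary endothelium and was named after its values were seen, rose from 2.13 ± 0.38 to 18.8 ± 3.04 CPM (log2 3.11 ± 0.38, adjusted p = 0.0436, n = 2 against 3). No gene was called lower in edgeR. At an unadjusted p under 0.05 there were 2418 genes, against 933 by chance, and the DESeq2 Wald test called 329 higher and 100 lower. Day 3 and uninjured libraries did not overlap for 34.1% of genes, where chance gives 20%.

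Several matrix, contractile and PDGF receptor genes had positive fold changes at day 3, and none of them passed over all genes. Col1a1 was at 532 ± 287 CPM (log2 2.04 ± 0.41, adjusted p = 0.152), Col1a2 at 641 ± 401 CPM (adjusted p = 0.186), Fn1 at 73.2 ± 53.5 CPM (adjusted p = 0.187) and Postn at 34.9 ± 3.41 CPM (log2 1.38 ± 0.35, adjusted p = 0.190). Of 29 matrix genes, 0 passed over all genes and 5 rose adjusted over the list alone (median 0.83, camera adjusted p = 2.27e-05, adjusted p = 0.807 with an estimated correlation). Acta2 was at 76.7 ± 56.7 CPM and Tagln at 6.28 ± 4.20 CPM (adjusted p = 0.186 and 0.220). Of 17 contractile genes, 11 had a positive fold change, 0 passed over all genes, and 4 rose and 1 fell adjusted over the list alone (median 0.67, camera adjusted p = 0.0544, adjusted p = 0.833 with an estimated correlation), with Tpm1 and Tpm2 at log2 fold changes of -0.827 and -0.883. Pdgfra, Pdgfrb and Pdgfb were at 19.8 ± 10.8, 16.3 ± 7.86 and 5.31 ± 1.41 CPM (adjusted p = 0.310, 0.319 and 0.344), and Pdgfa at 24.3 ± 10.1 CPM. The PDGF list as a whole had a median of -0.31 (21 genes, 0 passed over all genes or adjusted over the list alone, camera adjusted p = 0.475). Col3a1, Cd34, Ly6a and Ptprc had log2 fold changes of 0.92, 0.25, 0.41 and 1.16 with none passing.

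Genes of adipocyte identity lay lower on average at day 3 as well, and none passed singly. Adipoq was at 3583 ± 359 CPM (log2 -0.55 ± 0.44, adjusted p = 0.612), Plin1 at 742 ± 76.6 CPM, Pparg at 189 ± 8.12 CPM and Fabp4 at 23590 ± 6197 CPM, and Fasn and Lep had log2 fold changes of -0.75 ± 0.49 and -1.14 ± 0.44 (adjusted p = 0.538 and 0.319). Adipoq, Plin1, Pparg and Lep were lower in both day 3 libraries than in each uninjured library, whereas Fasn and Fabp4 overlapped. Of 20 identity genes, 0 passed over all genes or adjusted over the list alone (median -0.30, camera adjusted p = 0.0254, adjusted p = 0.833 with an estimated correlation).

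Erythroid, macrophage, cytokine and neutrophil lists had the highest medians of the 31 lists at day 3, without a single gene passing over all genes. Adjusted over the list alone, 4 of 5 erythroid genes (median 1.95, camera adjusted p = 6.35e-05), 14 of 18 macrophage and monocyte genes (median 1.72, camera adjusted p = 1.06e-11), 9 of 18 cytokine and chemokine genes (median 1.67, camera adjusted p = 1.90e-07) and 2 of 10 neutrophil genes (median 1.61, camera adjusted p = 0.000359) rose, each list with an adjusted p = 0.467 with an estimated correlation. The macrophage score was 0.71 in day 3 replicate 1 and 2.46 in replicate 2. Endothelial genes had a median of 1.35 (6 of 14 rose adjusted over the list alone, camera adjusted p = 4.93e-07, adjusted p = 0.564 with an estimated correlation), and skeletal muscle genes of -0.75 (1 of 16 fell adjusted over the list alone, camera adjusted p = 4.90e-05, adjusted p = 0.664 with an estimated correlation). In all, camera called 11 lists higher and 4 lower at day 3 at the preset correlation and 0 with an estimated correlation. Median, mean and test differed in sign for basement membrane (-0.24, 0.06, lower), TGF-beta (-0.25, 0.43, higher), Schwann cell and melanocyte (-0.13, 0.17, higher) and T, B and NK cell genes (0.01, 0.05, lower), none of them called.

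The day 3 counts rest on few libraries. Without day 3 replicate 1 there were 13 genes, without replicate 2 there were 150, and without day 7 replicate 3, which enters through the shared dispersion, 34; without any 1 of the uninjured libraries or day 7 replicates 1 and 2 there were 0.

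Between day 3 and day 7, 12 genes rose, several of them of secreted or matrix proteins. None of these had passed at day 3 against uninjured skin, where only 2 genes passed in all. In that contrast Prss35, C1qtnf3, C1qtnf2 and Mfap4 had negative fold changes, and the others had higher means at day 3 than in uninjured libraries. Cthrc1 had a log2 fold change of 2.243 ± 0.355 there (edgeR adjusted p = 0.114). Spp1 was at 2.67 and 3.96 CPM at day 3 and at most 0.98 CPM in uninjured libraries. Cthrc1, a secreted protein of repairing tissue, went from 3.31 ± 0.31 (n = 2) to 109 ± 28.3 CPM (n = 3), 32.5-fold (log2 5.02 ± 0.34, adjusted p = 0.000197). Postn rose 16.3-fold (34.9 ± 3.41 to 570.5 ± 155 CPM, adjusted p = 0.00499) and the small leucine-rich proteoglycan Aspn 18.1-fold (5.72 ± 4.01 to 108 ± 27.3 CPM, adjusted p = 0.00547). Osteopontin, Spp1, rose 18.1-fold, the macrophage elastase Mmp12 19.5-fold, Lrrc17 17.5-fold, C1qtnf3 30.5-fold and the protease-like Prss35 78.9-fold, and Lrrc15 went from 1.74 ± 0.72 to 55.02 ± 13.5 CPM. Mfap4, Tmem119 and C1qtnf2, named after their values were seen, rose by 3.27, 3.12 and 4.36 on the log2 scale. Prtn3, proteinase 3, fell by 3.14 on the log2 scale (634 ± 364 to 71.8 ± 25.6 CPM, adjusted p = 0.0313), the muscle gene Mybpc2 by 2.67, the AMP deaminase Ampd3 by 1.94 and Sh2d4b, named after its values were seen, by 2.63.

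In this contrast, 12 genes were higher and 4 lower (2054 at an unadjusted p under 0.05, against 933 by chance). With upper-quartile scaling the split was 15 higher and 11 lower. Of 29 matrix genes, 1 rose over all genes and 16 adjusted over the list alone (median 1.32, camera adjusted p = 5.74e-24, adjusted p = 0.266 with an estimated correlation). Col1a1 and Col1a2 had log2 fold changes of 2.04 ± 0.44 and 1.99 ± 0.47 (adjusted p = 0.162 and 0.217). Pdgfrb and Pdgfb had log2 fold changes of 0.81 ± 0.55 and 1.12 ± 0.56, Pdgfra of -0.11 ± 0.52, Adipoq of -0.14 ± 0.43, Plin1 of -0.44 ± 0.33 and Lep of 1.08 ± 0.44, and none passed. Other fixed genes, Fn1, Acta2, Tagln, Col3a1 and Cd34, had log2 fold changes of 0.96, 0.97, 1.54, 1.06 and 1.43 and did not pass either. Camera called 12 lists higher and 4 lower at the preset correlation and 0 with an estimated correlation. Median, mean and test differed in sign for macrophage (-0.13, 0.04, higher), neutrophil (-0.26, 0.08, higher), unfolded protein response (0.08, -0.05, lower) and erythroid genes (0.44, 0.21, lower), none of them called. The number of genes was 34 and 26 without day 3 replicates 1 and 2, and 7 and 5 without day 7 replicates 1 and 2.

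The 2 genes called at day 3 were called in the same direction at day 7, where independent lists of these sizes would share 0.118 genes. Across all genes, the log2 fold changes of both contrasts had a Pearson correlation of 0.71 and a covariance of 0.80. Unchanged groups simulated against the same uninjured libraries gave a mean correlation of 0.43 and an overlap of 0 genes in 20 runs. With no group changed, few genes can be called at either time, so that overlap is no reference for the 2 shared genes. The mean simulated covariance was 0.13, which the measured one exceeded by 0.68. Genes are not independent replicates, and with 3 uninjured libraries the controls could not be split into sets of at least 2, so part of the excess may come from the shared controls. Of the 1101 genes higher at day 7, 1059 also had a positive fold change at day 3, with a median log2 fold change of 1.41 there and 2.59 at day 7. These genes were selected against the same uninjured libraries. An unchanged day 3 was therefore simulated beside the measured day 7 means, with genes varying independently. In it, 57.8% of the genes higher at day 7 had a positive fold change at day 3 (mean of 20 runs, highest 60.9%), with a median of 0.135. The measured share was 96.2%. Of genes lower at day 7, 66.7% had a negative fold change at day 3 in the simulation (highest 69.1%), against 94.8% measured. The simulation called a mean of 2372 genes higher and 1292 lower, more than the 1101 and 330 measured. Its selected sets thus differed from the measured ones, and the shares are not like for like. The number of genes changed in the same direction at both times was 7 and 112 without day 3 replicates 1 and 2, 32 without day 7 replicate 3, and 0 without any 1 of the other libraries.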

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

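In this part, the tests of luminal epithelium, of keratinocytes, of a response of adipocytes, of RNA outside tagged ribosomes, of a lower adipocyte share and of the spread within day 3 were chosen after the results they bear on were seen, as were the covariate for luminal epithelial RNA and the simulation of an unchanged day 3; the bound used for the spread was also set after its value was known.

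A direct test between the wound times drew attention to 12 named genes. Log2 fold changes at day 7 against day 3 were 5.02 for Cthrc1, 4.03 for Postn, 4.18 for Aspn, 4.91 for Lrrc15, 4.13 for Lrrc17, 4.93 for C1qtnf3, 6.30 for Prss35, 4.18 for Spp1 and 4.29 for Mmp12, and -3.14, -2.67 and -1.94 for Prtn3, Mybpc2 and Ampd3. The same comparison drew attention to 16 lists through camera at the preset correlation, none of which was called with an estimated correlation. Median log2 fold changes were 1.32 for fibrillar matrix, 0.51 for basement membrane, 0.95 for contractile genes, 1.06 for matrix proteases, 0.75 for fibroblast markers, 0.35 for PDGF signalling, 0.46 for TGF-beta, 1.64 for Wnt, 0.40 for interferon response, 1.42 for cell cycle, 0.65 for mitochondrially encoded genes and 0.92 for T, B and NK cell genes. They were -0.38 for adipocyte identity, -0.32 for fatty acid oxidation, -0.79 for the nuclear respiratory chain and -1.498 for skeletal muscle.

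Genes of luminal epithelium were high in the 3 day 7 libraries and in day 3 replicate 1, and much lower in day 3 replicate 2. Of 18 luminal genes listed before their values were looked at, 15 rose at day 7 (median 5.34, or 5.06 with genes at 0 set to their bound, 3 counts per library), and they were higher in day 3 replicate 1 than in replicate 2 by a median of 3.19, above all 10000 random lists. Without Foxa1 and Cldn3, which the naming rule also picked, 13 of 16 rose (median 4.52), with a median difference of 3.03 above all 10000 random lists. The comparison sets single libraries against each other, and genes of the random lists were drawn independently. Any list whose genes vary together could exceed them, so it does not tell epithelium in the tissue from a response of adipocytes. Keratinocytes as the source are argued against, since their markers had a median of 0.65 at day 7 against 5.47 for the luminal genes. Luminal epithelium in the collected tissue, carried past the pull-down of GFP-tagged ribosomes, is a candidate explanation, and uninjured levels of its markers differed, with no count of Csn3 or Prom1, Epcam at 8.23 to 9.06 CPM and Prlr at 34.4 to 47.96 CPM. A response of adipocytes stays open, since of 23 luminal genes that rose at day 7 all lay above each uninjured library in day 3 replicate 1 and 16 in replicate 2 (Slc5a5 at 7.59 CPM against at most 0.14, Krt19 at 4.28 against at most 1.29), while Krt8 at 0.64 CPM there lay within the uninjured range of 0.43 to 0.67 CPM.

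Matrix genes higher at day 7 may include RNA that was not bound to tagged ribosomes. Nuclear and untranslated RNAs were higher too, with a median of 1.91 over 10 genes of which 5 passed (camera p = 7.37e-08, p = 0.0690 with an estimated correlation), or 1.61 over 7 genes of which 2 passed without Meg3, Rian and Mirg of the imprinted Dlk1 locus (camera p = 0.000808, p over 0.05 with an estimated correlation), and Malat1 went from 450 to 468 CPM in uninjured to 885 to 4348 CPM in day 7 libraries. In the day 3 libraries Malat1 was at 1077 and 1526 CPM, above day 7 replicate 3 at 885 CPM. Postn was at 32.49 and 37.31 CPM at day 3 and at 477.56 CPM in that replicate, so Malat1 did not follow Postn across these libraries. Meg3 was higher in that replicate (55.58 CPM) than at day 3 (21.39 and 51.42 CPM). A lower adipocyte share with an otherwise unchanged mix of other cells is argued against, since skeletal muscle markers had a median of -2.35 while endothelial ones had 2.28. A lower share together with a changed mix of other cells is not excluded. Skeletal muscle was the only other cell type with a negative median. With the luminal covariate, the log2 fold change of Postn was 5.41 ± 0.37 before and 5.40 ± 0.68 after and that of Col1a1, which lost its call (adjusted p = 0.0773), 4.08 ± 0.42 and 4.89 ± 0.76; over the 1431 called genes the median fold change in the called direction went from 2.45 to 1.93 on the log2 scale and the median standard error from 0.49 to 0.87, where the covariate tracks the groups. Matrix RNA made by marked cells, by other cells in the wound, or a batch shared with the group cannot be told apart here, since each group has its own column prefix.

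Few genes were called at day 3. The number of libraries alone, with changes as large as at day 7, is argued against, since the comparison at day 7 called at least 386 genes with 2 day 7 libraries. These fits called 393, 386 and 4055 genes, against 1431 with 3 libraries, so the number and choice of libraries did alter the count. How many genes 2 libraries can show where changes are smaller was not tested by this. A larger spread within day 3 stays open, since its biological coefficient of variation of 38.8%, against 38.5% within day 7, rests on 1 pair and lies among the 28.7% to 47.9% of pairs of day 7 libraries, and 13 and 150 genes were called without day 3 replicates 1 and 2. Smaller changes at day 3 stay open as well. The genes higher at day 7 had a median log2 fold change of 1.41 at day 3 and 2.59 at day 7, values that share their controls. Simulations with an unchanged day 3 gave a mean of 0.135 at day 3. They called more genes higher at day 7 (a mean of 2372, against 1101 measured), so this value is not a matched reference.

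The 6 uninjured and day 7 libraries make 10 splits into 3 and 3, which are too few for a share under 0.05. In a fit of these groups alone, the real split gave 1142 genes higher and 320 lower, each reached by 1 of the 10 splits, and the highest other split gave 0. It gave 23 lists, reached by 2 of the 10 splits, and the highest other split gave 25.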

How the results depend on the processing

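The covariate for luminal epithelial RNA was chosen after the result was seen; the other settings were planned. Single genes, gene list tests and counts of list members past the threshold were followed together, and 4229 alternative values stayed the same. For a gene or list test this means the same direction and side of the threshold, and for a count a change of at most 1.5-fold. Of the others, 524 lost and 94 gained a call, 398 counts moved further and 91 values changed direction. Among the 93 genes named at day 7, none was lost with another scaling, filter or the DESeq2 Wald test where a value could be had, 91 were lost with the covariate, 28 with limma-voom, 23 with a fold threshold of 1.5, and 49, 25, 38, 38 and 44 without uninjured replicates 1, 2 and 3 and day 7 replicates 1 and 2. Without a filter, 38669 genes were tested, with infinite prior degrees of freedom against 6.07. Where 1 library was left out, fewer samples were fitted, and a lone day 3 library was assumed to vary like the other groups. With the covariate, median standard errors were larger and the median fold change of the day 7 calls smaller. For other settings, no filter among them, the cause was not tested. Upper-quartile scaling moved the median of all genes at day 3 to 0.13 from 0.02, and the shallowest library limits calls of low genes.

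Genes higher at day 3 (2) numbered 696 with no low-count filter, 0 with the filter of 5 CPM, 329 with the DESeq2 Wald test, 0 with limma-voom, 0 with only the 2 groups compared, 0 at a fold threshold of 1.5, and 0 to 129 when 1 library was left out. Genes lower at day 3 (0 in edgeR) numbered 230 with no filter, 100 with DESeq2 and 0 to 21 when 1 library was left out. At day 7, genes higher (1101) numbered 2362 with no filter, 1857 with DESeq2, 552 with limma-voom, 557 at the fold threshold, 7 with the covariate and 238 to 2616 when 1 library was left out, and genes lower (330) numbered 794, 644, 242, 130, 0 and 76 to 1439. At day 7 against day 3, genes higher (12) numbered 369 with no filter, 149 with DESeq2, 6 with limma-voom, 7 with the covariate and 4 to 23 when 1 library was left out. Genes lower (4) numbered 8 with DESeq2 size factors, 11 with upper-quartile scaling (57.7% of calls higher, against 75.0%), 203 with no filter, 86 with DESeq2, 1 with limma-voom, 1 with only the 2 groups, 1 at the fold threshold, 2 with the covariate and 0 to 12 when 1 library was left out. Genes changed in the same direction at both times (2) numbered 740 with no filter, 0 with the filter of 5 CPM, 335 with DESeq2, 0 with limma-voom, 0 with only the 2 groups, 0 at the fold threshold, 1 with the covariate and 0 to 112 when 1 library was left out. Gene lists called over the 3 contrasts (53) numbered 0 with an estimated correlation and 6 with fry.

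Whether replicate numbers pair the libraries is not settled. Deviations of the 7 same-numbered pairs correlated at -0.07 to 0.20, 2 of them over 0.1, and 4 of 8 libraries correlated best with their own number. Deviations of the 2 day 3 libraries from their mean mirror each other, so pairs with them say little. With the replicate block, genes higher and lower numbered 5 and 2 at day 3, 1563 and 568 at day 7, and 95 and 31 at day 7 against day 3, with 6 changed in the same direction at both times. With this block, log2 fold changes were -0.05 for Cd34 and -0.17 for Pdgfa at day 3 and 0.27 for Pdgfra at day 7 against day 3. List tests that changed direction with it had adjusted p of 0.643 (Schwann cell and melanocyte), 0.640 (fatty acid oxidation), 0.722 (fibroblast and progenitor markers), 0.584 (keratinocyte and hair follicle) and 0.903 (pericyte and vascular smooth muscle) at day 3, and 0.694 (cytosolic ribosomal proteins) at day 7 against day 3.

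Directions of genes that had not passed also changed. At day 3, log2 fold changes when 1 library was left out ran from -0.47 to 0.78 for Cd34, -0.44 to 1.59 for Col3a1, -0.034 to 0.59 for Fabp4, -0.45 to 0.40 for Pdgfa and -0.53 to 1.87 for Ptprc, and with the covariate were -0.023 for Fabp4, -0.57 for Pdgfa and 0.016 for Plin1, and -0.10 for Pdgfa with limma-voom. At day 7 they ran from -0.34 to 0.39 for Lep and -0.11 to 0.49 for Ly6a, and with the covariate were -0.10 for Fabp4, 0.30 for Lep and -0.39 for Pdgfa. At day 7 against day 3 they ran from -0.64 to 0.13 for Adipoq, -0.17 to 0.36 for Fabp4, -0.43 to 0.13 for Ly6a, -0.58 to 0.61 for Pdgfra and -0.49 to 1.91 for Ptprc, and with the covariate were 0.029 for Adipoq, -0.079 for Fabp4, 0.042 for Ly6a and 0.26 for Pdgfra, and -0.02 for Fabp4 with upper-quartile scaling.

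The ranges of adjusted p in this paragraph span fits of both directions, so a low end can belong to a rise or to a fall. Macrophage and monocyte genes at day 7 against day 3, for example, turned lower without day 3 replicate 1, a fit with 1 day 3 library. Of list tests that changed direction, only the nuclear respiratory chain at day 3 had been called (adjusted p = 0.0320). It had 0.372 with the covariate and 1.63e-06 to 0.120 when 1 library was left out, and turned lower without day 3 replicate 1 (adjusted p = 0.0798). Others at day 3 had, when 1 library was left out, adjusted p of 0.258 to 0.951 (PDGF ligands, receptors and pathway members), 0.418 to 0.953 (Schwann cell and melanocyte), 0.135 to 0.976 (T cell, B cell and NK cell), 0.0293 to 0.865 (TGF-beta pathway and target genes), 0.135 to 0.915 (basement membrane), 0.0484 to 0.924 (fatty acid oxidation), 0.0526 to 0.774 (fibroblast and progenitor markers), 0.00414 to 0.791 (keratinocyte and hair follicle) and 0.367 to 0.956 (pericyte and vascular smooth muscle). With the covariate they were 0.387 (Schwann), 0.369 (T, B and NK cell), 0.414 (TGF-beta) and 0.639 (basement membrane), with upper-quartile scaling 0.922 (Schwann), with no filter 0.913 (Schwann) and 0.536 (T, B and NK cell), with only the 2 groups 0.928 (basement membrane), with the filter of 5 CPM 0.857 (pericyte) and without abundant background genes 0.709 (keratinocyte). At day 7 the ranges were 0.138 to 0.796 for Schwann cell and melanocyte (0.802 with the covariate) and 0.00727 to 0.500 for keratinocyte and hair follicle. At day 7 against day 3 they were 0.0466 to 0.653 (Schwann cell and melanocyte), 0.296 to 0.832 (cytosolic ribosomal proteins, with 0.971 under upper-quartile scaling and 0.931 with the covariate), 0.000122 to 0.815 (endothelial), 0.00109 to 0.862 (erythroid), 0.00112 to 0.899 (fatty acid and triglyceride synthesis), 0.129 to 0.878 (glycolysis and hypoxia response), 0.00109 to 0.280 (keratinocyte and hair follicle), 5.23e-05 to 0.768 (macrophage and monocyte), 0.220 to 0.959 (mast cell), 0.286 to 0.842 (neutrophil) and 0.147 to 0.815 (unfolded protein response and secretory load, with 0.693 with the covariate).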

Other observations

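Tests of the first 5 imprinted genes below and of nuclear RNAs were chosen after the results were seen, and the test of further imprinted genes was planned before their values were looked at. Noncoding RNAs of the Dlk1 locus, which is imprinted, rose at day 7 against uninjured skin with Dlk1. Meg3 rose by 5.02 ± 0.60 on the log2 scale (adjusted p = 0.00229), to 252, 288 and 55.6 CPM in the day 7 libraries from 5.24 to 7.22 CPM, and was at 21.4 and 51.4 CPM at day 3. Rian and Mirg rose by 3.63 ± 0.58 and 4.35 ± 0.72, and H19, an imprinted noncoding RNA of another locus, by 1.23 ± 0.33 (adjusted p = 0.0481). These 5 genes were picked because they were high (camera p = 8.26e-09, p = 0.00925 with an estimated correlation), so that test is not independent evidence. Xist, which silences an X chromosome and stays in the nucleus, was at most at 10.9 CPM in uninjured, 36.6 and 55.2 CPM in day 3 and 18.2 to 111 CPM in day 7 libraries, and the Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y were at most at 1.56 CPM.

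A hypothesis was that imprinted growth genes rose in general at day 7. The planned test over 13 further tested imprinted genes did not show a general rise and cannot exclude one. Their median log2 fold change was 0.37 (camera p = 0.228, p = 0.573 with an estimated correlation), and 7 of the 13 had a positive fold change. Of these, Mest, Ndn and Igf2r rose by 2.02, 1.15 and 1.18 on the log2 scale, and Nnat, at 982, 1283 and 569 CPM in uninjured libraries, was at 155, 430 and 453 CPM at day 7 (adjusted p = 0.111). Meg3, Rian and Mirg also belong to the list of nuclear and untranslated RNAs, which had a median of 1.91.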
